A study of Homo sapiens with 2 samples.

How the data were processed

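Gene expression was measured on 2 Agilent 2-colour oligonucleotide arrays, 1 for each of the human prostate cancer cell lines LNCaP and PC3. Per the labels, each line was infected with lentivirus carrying short hairpin RNA (shRNA) against STMN1 or non-targeting shRNA, stable cells were selected with 1 µg/ml puromycin, and cells were grown in RPMI medium with 10% fetal bovine serum. Whether each array holds 1 or several STMN1 hairpins is not given in the sources used here. Total RNA was column-purified and amplified from an oligo-dT primer carrying a T7 promoter, per the labels. The STMN1 shRNA sample carried Cy3 (green) and the non-targeting sample Cy5 (red) on both arrays, per the labels. There was no array with the dyes swapped and no second array of either line, so the number of arrays limits the precision.

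The spot intensities were deposited as scanner output of Agilent Feature Extraction 9.5.1.1 for array design 014850, per the file headers, with a mean signal and a local background median for each dye. Probe coordinates refer to hg18 (NCBI build 36), per the file headers. The deposited scanner files also hold a processed intensity for each dye, background-subtracted and dye-normalized by the scanner software, and a log10 ratio of red over green with its error, per the file headers. They hold a p-value of that ratio from the scanner software's own model of spot error, per the file headers, which speaks of spots on an array and not of repeated cultures. Other deposited columns are flags of 0 or 1 for signal above background, saturation and outlying spots. The authors also deposited a table of log2 values for both arrays. How that table was made is not given in the sources used here. Set against the scanner values, its sign was that of knockdown over control, its scale was log2 with a slope of 0.994 in LNCaP and 0.984 in PC3, and its correlation was highest with loess-normalized signals that had no background subtraction (r across probes 0.984 and 0.975). Its column medians were -0.010 in LNCaP and -0.0085 in PC3, and whether the authors centred it by another route stays unknown.

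Each array held 45015 spots, of which 43376 were gene spots and 1639 controls, covering 41000 probes. Of these, 264 probes had 10 spots each. Spots called outliers by the scanner software (132 gene spots in LNCaP, 143 in PC3) were left out, and no probe was saturated. Median green and red signals were 217.6 and 193.9 in LNCaP and 226.4 and 184.2 in PC3, over background medians of 44 and 50 in LNCaP and 40 and 48.5 in PC3. In LNCaP 74.4% of probes were well above background in at least 1 channel, and in PC3 74.9%. Spots of the same probe differed with an SD of 0.073 log2 in LNCaP and 0.075 in PC3, and the scanner software's median error of a log2 ratio was 0.21 on both arrays. Spike-in RNAs gave the scanner software's own ratios a slope of observed on added log10 ratio of 0.881 in LNCaP and 0.882 in PC3. Those ratios were thus slightly compressed. On them the authors' log2 values had slopes of 0.717 in LNCaP and 0.733 in PC3, and on the loess ratios used here 0.997 and 0.991. The ratios used here therefore ran smaller than the scanner software's, and their own spike-in slope was not measured.

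Mean signals were background-corrected with normexp (offset 50) and normalized within each array by loess (span 0.3, control spots at weight 0) in limma 3.58.1 under R 4.3.3, with data.table (version 1.17.8). Every ratio was turned to knockdown over control. Spots of a probe were averaged. Old names were updated through RefSeq's human gene table (assembly GRCh38.p14, names only): 23958 probes matched by accession, 2755 by symbol and 1032 by an older symbol, while 13255 probes had no match and were not named. For the 7237 genes with several probes, out of 17843, the brightest probe by mean intensity over both arrays was used. A gene counted as measured in a line where its probe was well above background in at least 1 channel (14276 genes in LNCaP, 14503 in PC3). Where only 1 channel was above background, the ratio was read as a bound against the dim channel's own signal or, where higher, the lowest signal among probes above background in that channel.

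With 1 array per line there was no test within a line, and genes were listed by size, at 2-fold or beyond. The only fit with residual degrees of freedom took both lines as repeats of the same knockdown (limma, lmFit and eBayes of the log2 ratio against 0, Benjamini-Hochberg adjustment, 13519 genes measured in both lines, 1 residual degree of freedom, 5.77 prior degrees of freedom). It measures the spread between lines, and any probe-specific dye bias common to both arrays counts in it as an effect. For 24 gene lists the median log2 ratio was set against 10000 random lists of the same size, matched on mean intensity in 20 bins. A percentile from these describes an array and is not a test across cultures. Random lists were drawn only from the loess values of the probes used. Where a median of another setting is set against their range, that range is not the setting's own. Lists with fewer than 5 measured genes were given no percentile.

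Genes named in the text were the target, the 12 highest and 12 lowest genes per line at 2-fold or beyond with both channels above background, the 3 largest bounds each way per line, the 10 genes each way with the largest change common to both lines, the 5 genes each way that differed most between lines with both channels of both arrays above background, and up to 4 members per list and line at 2-fold or beyond. Genes with only a locus, clone, accession or chromosome open reading frame name were passed over. Some genes that the rule takes are not reported here. Members of lists below 2-fold are named as examples and were chosen after their values were seen. The tests, the gene lists, the naming rule and the alternatives were fixed before the data were examined, apart from those named as later in the closing section. Alternatives were signals without background correction, the scanner software's processed signals, median centring in place of loess, the authors' deposited log2 table, the mean over all probes of a gene, looser and stricter filters on dim probes, a 3-fold rule, the scanner p-value as a further filter and an intensity trend in the variance.

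The steps were tested on simulated data: 2 arrays were drawn from the signals of the real spots, with 200 of 24520 probes changed 3- or 4-fold, a dye curve and spot noise. In the simulated LNCaP comparison the 2-fold rule recovered 99% of probes changed 3-fold and 100% of those changed 4-fold, and called 0 unchanged probes. The limma fit over both simulated arrays recovered 100% of both and also called 47 unchanged probes at adjusted p under 0.05, more than its nominal rate. The changed probes were bright ones, and the simulated ratio noise was set below the scanner software's median error of 0.21. No culture variation or probe-specific dye bias was drawn. The 0 calls of the 2-fold rule followed from these settings and give no rate of false calls on the real arrays. A simulated list shifted by 0.4 log2 came out at a median of 0.35 and at percentile 100 of random lists. Plots were drawn with matplotlib 3.10.9 and pandas 2.3.3 under Python 3.11.15.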

Results

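The series asked how lowering STMN1 changes gene expression in prostate cancer cells. STMN1 encodes stathmin, a protein that binds tubulin dimers and destabilizes microtubules. LNCaP is an androgen-responsive line from a lymph node metastasis, and PC3 is an androgen-independent line from a bone metastasis. In each line, stable cells carrying shRNA against STMN1 were compared with cells carrying non-targeting shRNA on 1 array per line, 2 arrays in all. There were no replicates within a line, and all values are log2 ratios of knockdown over control. Where an error is given it is the scanner software's error of the log2 ratio, which covers spots on that array and not repeated cultures.

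STMN1 was the lowest of all measured genes in both lines. Its log2 ratio was -3.54 in LNCaP (scanner error 0.39), which is 11.6-fold lower than control, and -3.41 in PC3 (scanner error 0.38), which is 10.7-fold lower. The probe lies on chromosome 1 at 26099680 to 26099739 (hg18). It was bright in both controls, at log2 signals of 15.24 in LNCaP and 15.43 in PC3. Over both lines the mean was -3.48 with a standard error of 0.13 in limma (adjusted p = 0.000617), and STMN1 was lower in 2 of 2 lines. A second, dim probe that maps to STMN1 by an older gene name stood at -0.14 in LNCaP and 0.033 in PC3. Averaging both probes ended the call (limma adjusted p = 0.134), while under the other settings limma's adjusted p lay between 1.67e-05 and 0.026.

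Control cells of the 2 lines differed in several of the genes listed as typical of each. In the control channel the luminal prostate genes FOLH1 and KLK2 had log2 signals higher in LNCaP by 9.10 and 6.68. PLAU, MET and LAMB3 were brighter in the PC3 control, with LNCaP minus PC3 differences of -11.26, -7.88 and -7.60. Other listed genes differed little, with HOXB13 at 0.59, KRT18 at 0.30 and EGFR, from the PC3 list, at 0.72. The value of KLK3, which encodes prostate-specific antigen, is doubtful although it counts in the gene lists, because its brightest probe had nearly equal control signals in LNCaP and PC3 (16.06 and 16.05) while its other 2 probes had 13.08 and 15.42 in LNCaP against 6.53 and 5.94 in PC3.

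In LNCaP, DIO3, HSPA6, CRYAB and ID1 were the highest genes with the STMN1 shRNA. DIO3, the deiodinase that inactivates thyroid hormone, had the highest log2 ratio at 4.34. HSPA6, a strictly inducible member of the Hsp70 family, stood at 3.72, and CRYAB, the small heat shock protein alpha-B crystallin, at 3.30. ID1, an inhibitor of basic helix-loop-helix factors and a BMP target, was at 2.79. The ubiquitin-like modifier UBD, which inflammatory cytokines induce, was at 2.5 and the secreted phospholipase PLA2G2A at 2.51.

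The other genes among the 12 highest in LNCaP were MUC20 (2.68), the lipid transporter ABCA12 (2.67), the ubiquitin ligase NEURL3 (2.47), the glucuronosyltransferase UGT1A6 (2.45), the actin-binding kelch protein ENC1 (2.43) and NDRG4 (2.38). The scanner errors of these 12 log2 ratios ran from 0.31 to 0.46. UGT1A6 shares most exons with its neighbours in the UGT1A locus, and MUC20 has near-identical copies, so both are uncertain as to the gene. Their other probes read 1.27 for UGT1A6 and 1.48 for MUC20. By the probes used, KRT75 was at least 4.62-fold higher, RSAD2 at least 2.52-fold and MMP12 at least 2.32-fold, their control channel being not well above background. The other probe of RSAD2 had a log2 ratio of 0.25 and that of MMP12 0.84.

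Genes lower in LNCaP after STMN1 itself were led by the hormone gene RLN2 (relaxin 2) at -2.38 and TNFRSF19, a receptor of the TNF superfamily, at -1.93. RLN1, the neighbour of RLN2, stood at -1.88, and these near-identical copies leave it uncertain which of them was lower. GINS4, a subunit of the replicative helicase, was at -1.63. RGS2 and GNB4, both of G protein signalling, were at -1.59 each. LUZP2 (-1.47), the O-glycosylation enzyme GALNT7 (-1.46), the collagen cross-linking enzyme LOX (-1.38), REPS2 (-1.37) and the thioredoxin-binding TXNIP (-1.35) completed the list. Their scanner errors ran from 0.24 to 0.31. Other probes read up to -0.55 for TNFRSF19 and -0.475 for GNB4. The largest bounds among genes lost to background were small, at least 1.46-fold lower for PNLIPRP2, 1.36-fold for BEX5 and 1.31-fold for OR2W3.

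In all, 163 genes were at least 2-fold higher and 50 at least 2-fold lower in LNCaP, 1.49% of the 14276 measured. The share of higher genes among these was 76.5%, and 63.6% with median centring in place of loess. Of 113 other probes for these genes, 92.9% had the same sign and 21.2% reached 2-fold themselves. The median absolute log2 ratio was 1.19 for the probes used and 0.55 for those other probes.

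Inflammatory and BMP-responsive genes were higher as groups in LNCaP. Of 19 measured NF-kB and inflammatory genes, 16 lay above 0, with a median of 0.49 that exceeded all random lists (percentile 100). BIRC3, an inhibitor of apoptosis induced by NF-kB, stood at 1.86, SAA1 at 1.78 (uncertain against its near-identical copy SAA2), IL32 at 1.15 and the NF-kB subunit gene RELB at 0.90. Of 17 TGF-beta and BMP response genes, 16 lay above 0 (median 0.29, percentile 99.9), with ID2 at 1.36 and ID3 at 1.13 beside ID1. Interferon response genes had a median of 0.136 (percentile 97.9, 17 of 32 above 0), which barely passed the upper limit of random lists (0.132) and lay under it in every other setting except that without background correction. ISG15 stood at 0.91, and RSAD2 had a control not well above background. Without a filter on dim probes the medians were 0.16 for NF-kB, 0.21 for TGF-beta and BMP and 0.067 for interferon genes, and the scanner software's processed signals gave 0.91 for NF-kB and 0.57 for TGF-beta and BMP.

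Cholesterol synthesis, invasion and PC3 identity genes were also higher in LNCaP as groups. Of 22 cholesterol synthesis genes, 20 lay above 0 (median 0.23, percentile 99.6), none at 2-fold, with the synthesis enzymes TM7SF2 at 0.86 and LSS at 0.69. Invasion and matrix proteolysis genes had a median of 0.20 (percentile 99.4, 17 of 24 above 0), led by the laminin chain gene LAMB3 at 2.31 and the protease gene MMP7 at 1.52. Genes typical of PC3 had a median of 0.40 in LNCaP (percentile 99.9, 7 of 9 above 0), among them LAMB3, the receptor gene MET at 1.09 and VIM at 1.03. MET had other probes down to -0.019. Without a filter on dim probes the medians were 0.057 for invasion and 0.16 for PC3 identity genes, inside the middle 95% of the random lists drawn with that filter, and with the scanner software's processed signals 0.36 and 1.06. The invasion median also lay inside, at 0.137, with both channels above background. Epithelial genes stood at a median of 0.18 (percentile 98.2, 17 of 24 above 0) with ELF3 at 1.20. In some other settings the epithelial median lay under the upper limit of random lists drawn in the fit used (0.172). It was 0.059 in the authors' deposited log2 values and 0.158 with the scanner software's processed signals. With median centring it was 0.146, and without a filter on dim probes 0.143. Mesenchymal genes had a median of 0.081 (percentile 78.6), with FN1, fibronectin, at 1.82 (lowest of 3 probes 0.95), VIM at 1.03 and LOX at -1.38.

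Replication-dependent histone genes had a median of 0.22 in LNCaP (percentile 99.2, 17 of 22 above 0), with H2AC6 at 1.54, H2AC18 at 1.30 and H2BC12 at 1.06. Histone genes are near-identical copies of each other, so single members are uncertain, and a second H2AC6 probe read -0.036. Neuroendocrine genes had a median of 0.18 (percentile 98.1, 6 of 11 above 0), with the decarboxylase DDC at 1.51 and the neuronal enolase ENO2 at 1.12. That median was 0.44 with the scanner software's processed signals. In other settings it lay under the upper limit of random lists drawn in the fit used (0.17). It was 0.017 without a filter on dim probes, 0.084 with both channels above background, 0.131 over all probes and 0.14 without background correction.

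Mitosis, ribosomal protein and LNCaP identity genes were lower in LNCaP as groups. Of 35 mitosis genes, 31 lay below 0 and 4 above (median -0.23, percentile 0), with the phosphatase CDC25C at -0.83 and the kinetochore protein CENPF at -0.81. Of 30 ribosomal protein genes, 5 lay above 0 (median -0.27, percentile 0), with RPS2 at -0.81 and RPL14 at -0.77. The ribosomal median was -0.96 with median centring and -0.11 in the authors' deposited table. LNCaP identity genes had a median of -0.24 (percentile 0.13, 4 of 14 above 0), with SPDEF at -0.60 and HOXB13 at -0.40. ACP3, prostatic acid phosphatase, went the other way at 1.11, and its other probe read 0.54. The median of LNCaP identity genes was -0.55 under median centring. Over all probes (-0.096) and with the scanner software's processed signals (-0.114) it lay inside the middle 95% of random lists drawn in the fit used.

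The stress response list was lower in LNCaP by its median of -0.11 (percentile 0.65, 11 of 28 above 0), with the asparagine synthetase gene ASNS at -1.09 and the stress-induced factor ATF3 at 1.39, and the median was -0.29 with median centring. Other lists stayed within the middle 95% of random lists in LNCaP in the fit used. Some lay outside that range in other settings, for which no random lists were drawn. Among these were hypoxia and glycolysis genes (0.24 over all probes), p53 targets (0.18 with median centring), and fibroblast and leukocyte markers (-0.22 and -0.26 with the scanner software's processed signals). Androgen-responsive genes had a median of 0.14 (percentile 94.2), with ACP3 at 1.11 (other probe 0.54). The p53 targets had 0.15 (percentile 95.4, CDKN1A at 0.60), DNA replication genes -0.012 (20.3), hypoxia and glycolysis genes 0.073 (69.0), tubulins and microtubule regulators 0.044 (58.8, with the stathmin relative STMN4 at 1.17) and apoptosis regulators 0.033 (49.8). Markers of other cell types had medians of -0.11 for fibroblasts (percentile 10.5), -0.14 for leukocytes (3.77, with CD68 at 1.16), 0.19 for basal keratinocytes (92.9) and -0.062 for endothelium (27.4).

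**Figure D1:**
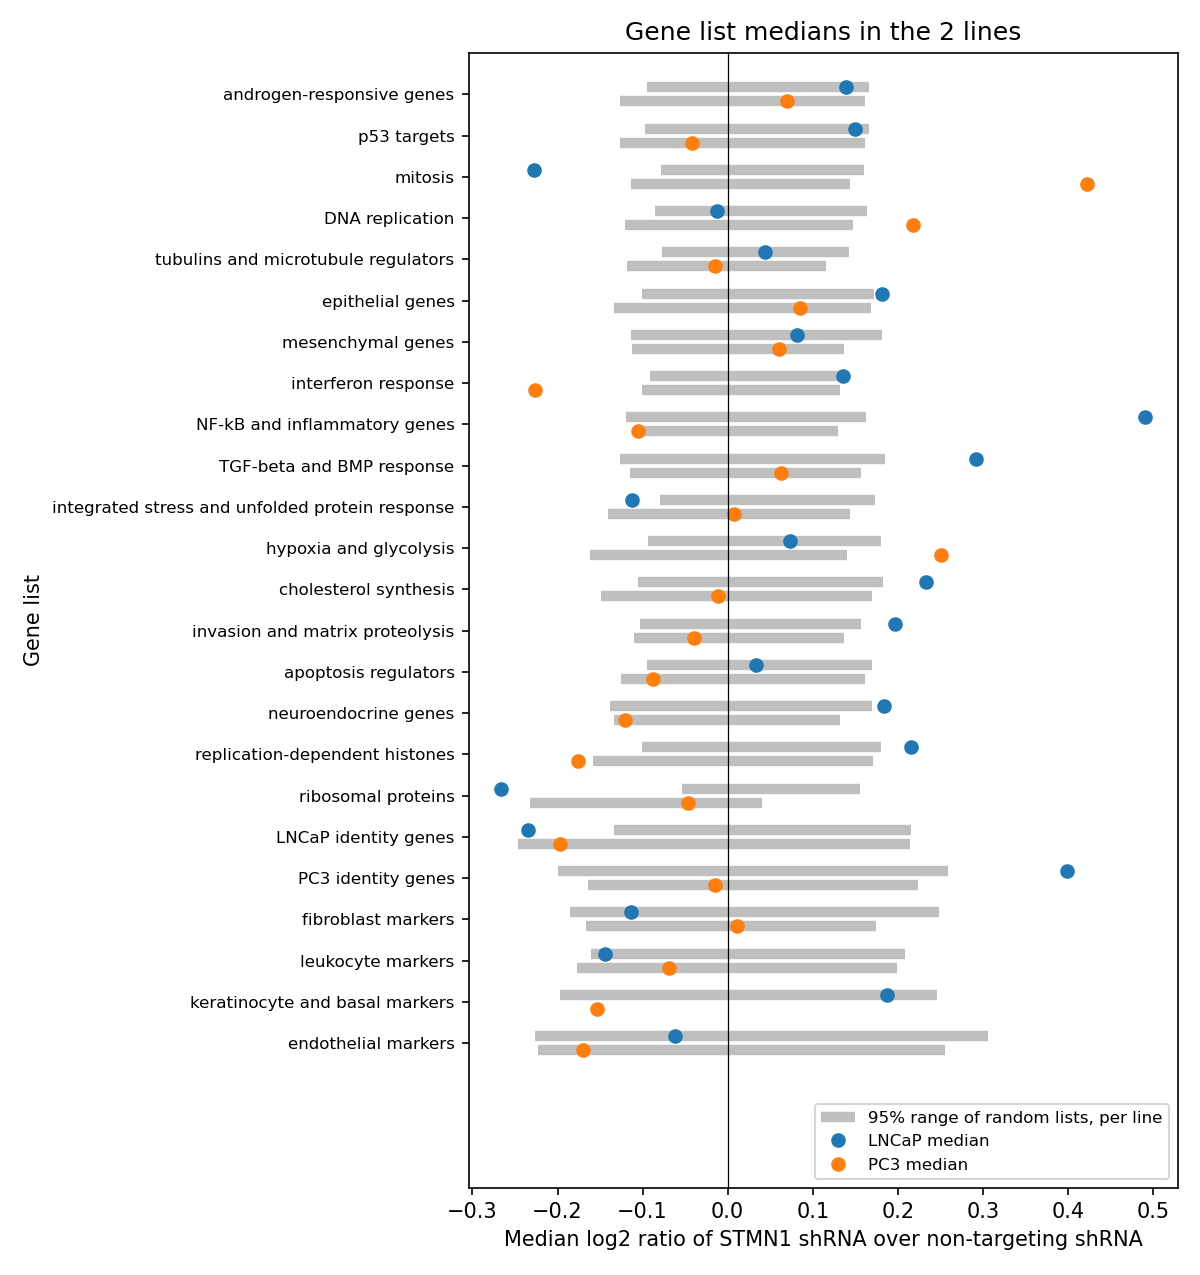
Median log2 ratio of STMN1 shRNA over non-targeting shRNA for each of 24 gene lists (points, LNCaP blue and PC3 orange), with grey bars for the central 95% of 10000 random lists matched on size and intensity in that line. Mitosis genes lie below their bar in LNCaP (-0.23) and above it in PC3 (0.42), and the basal list has no bar in PC3, where 4 of its genes were measured.

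In PC3, IDH3A, CFL1 and FLNA were the highest genes with the STMN1 shRNA, at smaller sizes than the highest genes of LNCaP. IDH3A, a subunit of mitochondrial isocitrate dehydrogenase, had the highest log2 ratio at 1.59, and its other probe read 0.39. CFL1, the actin-severing protein cofilin, stood at 1.5 with a second probe at 1.71, and FLNA, the actin cross-linker filamin A, at 1.34. NCKAP1, a subunit of the WAVE actin regulator, was at 1.14. The RNA-binding protein genes PABPC4 (1.24) and PCBP2 (1.19) and the splicing-associated WBP11 (1.24) were higher too, as was the glycolytic enzyme PKM (1.22, second probe 1.16). TRIM58 (1.23), KLHL5 (1.17), MSANTD2 (1.15) and the 14-3-3 protein gene YWHAE (1.15, lowest of 6 probes 0.76) completed the 12 highest, with scanner errors of 0.23 to 0.25.

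The lowest genes in PC3 after STMN1 included PLAT, FAM110C, KRT37 and ITGB3. Of these, PLAT, tissue plasminogen activator, was lowest at -1.87, and ITGB3, integrin beta 3, stood at -1.37. SERPINB2, an inhibitor of plasminogen activators, was at -1.21, and its other probe read -0.16. The endothelial proteoglycan gene ESM1 was at -1.20 and the growth factor binding protein FGFBP1 at -1.20. FAM110C stood at -1.60, the hair keratin KRT37 at -1.50, APOL6 at -1.34, the adaptor SKAP1 at -1.24, LRATD2 at -1.18 and CTPS1, the CTP synthase, at -1.17, with scanner errors of 0.23 to 0.27 for these 11 genes. APOL6 had other probes up to 0.033, and the other probe of LRATD2 read -0.21. Bounds were small: PCDH18 at least 1.47-fold, ACTL8 1.42-fold and CTSO 1.26-fold higher, UTS2 at least 1.48-fold, ADAMTS15 1.32-fold and TRIM63 1.30-fold lower. The other probe of UTS2 had a log2 ratio of -0.25.

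In all, 34 genes were at least 2-fold higher and 26 at least 2-fold lower in PC3, 0.414% of the 14503 measured. The share of higher genes was 56.7%, and 70.1% with median centring in place of loess, where 115 genes were higher and 49 lower. In the authors' deposited log2 values it was 47.8%, with 33 higher and 36 lower. Of 36 other probes for these genes, 91.7% had the same sign and 13.9% reached 2-fold.

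Mitosis, DNA replication and hypoxia genes were higher as groups in PC3. Of 35 mitosis genes, 31 lay above 0 (median 0.42, percentile 100), with the kinase gene NEK2 at 1.02, the checkpoint kinase BUB1B at 0.99 and the motor protein KIF20A at 0.96. DNA replication genes had a median of 0.22 (percentile 99.8, 26 of 30 above 0), with the ribonucleotide reductase gene RRM2 at 1.1 (lowest of 3 probes 0.10). Hypoxia and glycolysis genes had a median of 0.25 (percentile 99.99, 20 of 24 above 0), with the prolyl hydroxylase P4HA1 at 1.02 and GAPDH at 0.89. Over 7 other probes of 7 mitosis genes the PC3 median was 0.14, against 0.36 for the probes used.

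Interferon genes were lower as a group in PC3. Of 32 measured, 9 lay above 0 (median -0.23, percentile 0), with OASL at -0.92, MX1 at -0.82 and RIGI, a sensor of viral RNA, at -0.81. Histone genes had a median of -0.18 (percentile 1.47, 6 of 21 above 0) and NF-kB genes -0.11 (percentile 2.38, 11 of 27 above 0), with the chemokine CXCL1 at -0.71, IL1B at -0.67 and IL32 at 0.69. The NF-kB median of -0.105 barely passed the lower limit of random lists (-0.104), and the limit for histones was -0.158. In other settings both medians lay inside these limits, which were drawn from the loess values only. For NF-kB and histones they were 0.021 and -0.044 with median centring and -0.093 and -0.152 in the authors' deposited log2 values. Over all probes they were -0.08 and -0.14. The interferon median was -0.086 with median centring and -0.142 over all probes. With median centring the median of all PC3 genes was 0.104, against 0.006 in the fit used, so each of these lists stayed below it there. Invasion and matrix proteolysis genes had a median of -0.039 (percentile 21.8), though 3 members were at least 2-fold lower, PLAT, ITGB3 and the collagenase MMP1 at -1.15.

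Other lists in PC3 stayed within the middle 95% of random lists in the fit used. Some lay outside that range in other settings, for which no random lists were drawn. Among these were ribosomal protein genes (-0.48 with median centring, 0.14 in the authors' deposited log2 values), apoptosis regulators (-0.20 in the authors' values) and mesenchymal genes (0.17 with the scanner software's processed signals). Ribosomal protein genes had a median of -0.047 (percentile 76.8), LNCaP identity genes -0.20 (5.76), PC3 identity genes -0.015 (34.1), androgen-responsive genes 0.070 (77.9) and p53 targets -0.042 (21.9). Epithelial genes stood at 0.085 (82.3), mesenchymal genes at 0.060 (78.8), TGF-beta and BMP response genes at 0.063 (74.7), cholesterol synthesis genes at -0.011 (41.4) and stress response genes at 0.0070 (54.3). Apoptosis regulators had -0.088 (8.34), tubulins and microtubule regulators -0.015 (43.9) and neuroendocrine genes -0.12 (3.97). Markers of fibroblasts (0.011, percentile 55.7), leukocytes (-0.069, 24.6) and endothelium (-0.17, 6.0) and the 4 measured basal genes (-0.15) were near or below 0.

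Among genes well above background in both channels of both arrays, the lines differed most in those far higher in LNCaP and near or below 0 in PC3. LNCaP minus PC3 was 4.41 for DIO3, 3.90 for HSPA6, 3.40 for CRYAB, 2.88 for NEURL3 and 2.88 for NDRG4. In the opposite direction it was -1.97 for RLN1, -1.90 for LOX, -1.71 for TNFRSF19, -1.59 for GINS4 and -1.35 for PYGL, glycogen phosphorylase. PYGL itself stood at -0.98 in LNCaP and 0.38 in PC3. No gene was 2-fold higher in LNCaP and 2-fold lower in PC3 or the reverse (0 and 0 genes, against 0.162 and 0.0965 for independent lists).

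Mitosis genes differed between the lines as a group: the median of LNCaP minus PC3 was -0.62, with 0 of 35 genes above 0 and 8 at -1 or below. NEK2 (-1.33), CDC25C (-1.26), KIF20A (-1.16) and NUSAP1 (-1.05) differed most. The difference was -0.23 for DNA replication genes (percentile 0.01), -0.23 for ribosomal protein genes (percentile 0), 0.56 for histones (percentile 100), 0.45 for NF-kB genes (percentile 100), 0.34 for cholesterol synthesis genes (percentile 99.98), 0.24 for interferon genes (percentile 99.99), 0.22 for TGF-beta and BMP response genes (percentile 99.6), 0.21 for p53 targets (percentile 99.5), -0.14 for hypoxia and glycolysis genes (percentile 1.02) and -0.11 for stress response genes (percentile 2.14). Each line had 1 array, so none of these differences was tested against repeated cultures.

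**Figure D2:**
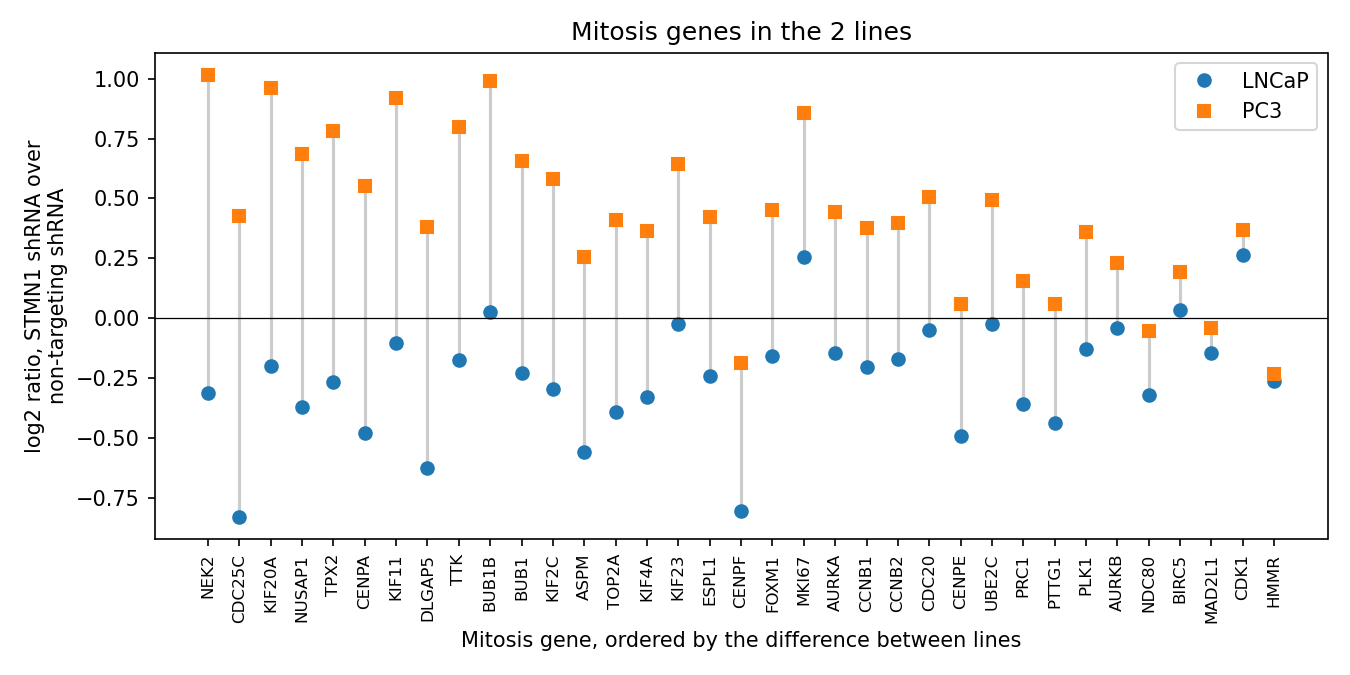
Log2 ratio of STMN1 shRNA over non-targeting shRNA for the 35 mitosis genes in LNCaP (circles) and PC3 (squares), ordered by LNCaP minus PC3, with a line joining the values of each gene. All 35 PC3 values lie above the LNCaP value of the same gene, with differences from -1.33 for NEK2 to -0.029 for HMMR.

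Few genes besides STMN1 were strongly lower or higher in both lines. FLNA (1.18 in LNCaP, 1.34 in PC3) and GEM, a small GTPase of cytoskeletal and calcium channel regulation (1.20 and 1.08), were at least 2-fold higher in both, GEM in LNCaP against a control not well above background (at least 2.30-fold), 2 genes where independent lists give 0.294. Besides the target STMN1, FAM110C (-1.27 and -1.60) and CEP290, a centrosome and cilium protein (-1.15 and -1.02), were at least 2-fold lower in both, 2 genes where independent lists without STMN1 give 0.0488. The next genes higher in both were IDH3A (1.00 and 1.59), FGFRL1 (0.98 and 1.02), FAM50B (1.20 and 0.96), STBD1 (1.40 and 0.95), the tetraspanin CD151 (0.86 and 0.86), RTN4 (0.90 and 0.85) and the lysosomal protease TPP1 (0.95 and 0.84). Those lower in both were RASD1 (-0.97 and -1.01), MRPS14 (-0.95 and -0.90), JDP2 (-1.1 and -0.89), RPS20 (-0.92 and -0.86), A2ML1 (-0.82 and -1.07), HLF (-0.82 and -1.07) and TMEM64 (-0.79 and -0.97).

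**Figure D3:**
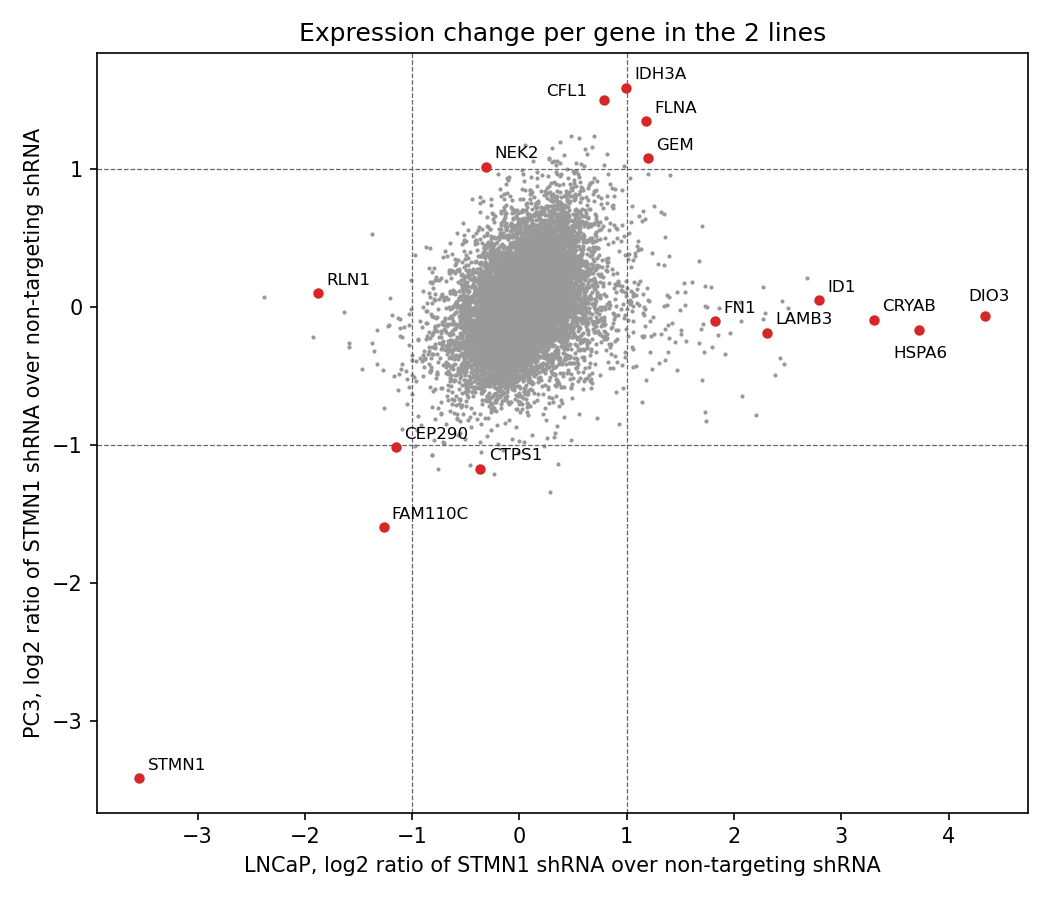
Log2 ratio of STMN1 shRNA over non-targeting shRNA for each of 13519 genes measured in both lines, LNCaP on the x axis and PC3 on the y axis, with dashed lines at 2-fold and named genes in red. STMN1 lies alone at -3.54 and -3.41, and DIO3, HSPA6 and CRYAB lie far right at PC3 values near 0.

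Across the 13519 genes measured in both lines, log2 ratios correlated at r = 0.336 (rho = 0.378), and 64.4% had the same sign, genes not being independent replicates. STMN1 was the only gene with limma's adjusted p under 0.05 over both lines, where 2216 genes had an unadjusted p under 0.05. The other genes named as common to both lines had limma adjusted p from 0.174 to 0.192. Both arrays had the same dye orientation, and other probes of CEP290, FAM110C, IDH3A, FGFRL1, RASD1 and TMEM64 gave smaller values: those of CEP290 read -0.62 and -0.38 in LNCaP and -0.23 and 0.015 in PC3, and that of FAM110C -0.47 and -0.60.

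Of 24 hypoxia and glycolysis genes, 9 passed limma over both lines when adjusted over the list alone, 8 higher and 1 lower, and none did over all genes. Their median in LNCaP alone, 0.073, lay inside the middle 95% of random lists. It was 0.24 over all probes, outside that range of the probes used, and -0.069 with median centring. ERO1A, a thiol oxidase of the endoplasmic reticulum, stood at 0.88 in LNCaP and 0.59 in PC3 (limma adjusted p = 0.0169 over the list alone), CA9, carbonic anhydrase 9, at 0.51 and 0.60, and GAPDH at 0.47 and 0.89. P4HA1, P4HA2, KDM3A, BNIP3L and ENO1 were also higher, and ANKRD37 was lower at -0.52 and -0.45.

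Smaller numbers passed limma when adjusted over the list alone in other groups. These were 4 of 27 androgen-responsive genes, 3 higher and 1 lower (ACSL3 and PMEPA1 among the higher), 4 of 11 LNCaP identity genes, all lower (among them HOXB13, SPDEF and KLK3, the last by its doubtful probe), 3 of 22 epithelial genes, all higher (CLDN7, JUP and OCLN), and 3 of 30 ribosomal protein genes, all lower (RPL14 and RPS2 among them). NF-kB genes had 2 of 18 (IL32 and NFKB2), while DNA replication (RRM2), invasion (ADAM9) and neuroendocrine genes (ENO2) had 1 each, all higher. The lowest RRM2 probe read 0.13 in LNCaP and 0.10 in PC3. The remaining lists, mitosis included, had 0, and no list had a gene that passed over all genes. Each list, hypoxia and glycolysis included, was adjusted on its own, with no correction for the number of lists. In the same fit 2216 of all 13519 genes had an unadjusted p under 0.05. Dye bias common to both arrays counts as an effect in it. Whether any list held more passing genes than random lists was not tested, so these counts do not establish a change specific to a list.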

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

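The tests of normalization and dye bias for the mitosis genes were chosen only after the result was seen, and the test of the genes' other probes was set down after the list medians were seen but before its own result.

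Mitosis genes were lower with the STMN1 shRNA in LNCaP and higher in PC3, with a median of LNCaP minus PC3 of -0.617 over 35 genes, and this opposite direction in the 2 lines was not tested against repeated cultures. Intensity-dependent normalization is argued against, since the smallest median difference under any other normalization or source was -0.615. Dye bias that is the same on both arrays cancels in this difference, so it alone leaves a value inside the central range of random lists (-0.11 to 0.15), which -0.617 is not. The choice of the brightest probe is argued against by 7 other probes of 7 of these genes, with a median difference of -0.464 and 7 of 7 below 0, although their PC3 median was 0.136 against 0.36 for the probes used. The growth state of the single cultures at harvest cannot be told apart from the knockdown with 1 array per line, so a difference in proliferation between the lines' responses to lower STMN1 may be considered only as a hypothesis.

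Histone genes had a median of LNCaP minus PC3 of 0.555, which was not tested. Their PC3 median was -0.044 with median centring, -0.152 in the authors' deposited log2 values and -0.14 over all probes. These values lay inside the range of random lists, which was drawn from the loess values only. NF-kB and inflammatory genes, such as BIRC3 and RELB, had a median difference of 0.445 that was not tested, but IL32 and NFKB2 were higher in both lines. The PC3 median of NF-kB genes was 0.021 with median centring, where the median of all PC3 genes was 0.104. Interferon response genes, such as OAS1 and OASL, had a median difference of 0.236 between the lines, which was likewise not tested.

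Probes with no gene symbol, which no comparison used, also held signal. In LNCaP 37 of them were at least 2-fold different (27 higher, 10 lower, of 8580 measured), and in PC3 25 were (18 higher, 7 lower, of 8481 measured).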

How the results depend on the processing

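The mitosis medians over the genes' other probes were added after the list medians were seen but before their own values, and the count without heat shock genes was chosen only after the results were seen. All 88 named values at 2-fold or beyond, STMN1 aside, kept their sign under the 5 other sources, normalizations and probe rules, with 391 of 440 alternative values within the scanner error and 49 moved beyond it. Signal over background limits dim genes, since only 74.4% of probes in LNCaP and 74.9% in PC3 were well above background in a channel. Each ratio sets knockdown against control on the same array. Pairing over repeated cultures was not possible because each line had 1 array and the labels give no replicate numbers. Leaving out a line leaves 1 array and no residual degrees of freedom, so that alternative gave no test. Where the values below moved, the cause was not tested.

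With the scanner software's processed signals the counts at 2-fold were 445 higher and 175 lower in LNCaP, 133 and 117 in PC3, and 15 and 10 in both lines, and r between lines was 0.277. Of the genes at 2-fold in LNCaP, 156 of 163 higher and 49 of 50 lower were kept. List medians in LNCaP were 0.912 for NF-kB, 0.565 for TGF-beta and BMP, 0.358 for invasion, 0.439 for neuroendocrine, 1.06 for PC3 identity, -0.129 for ribosomal and -0.114 for LNCaP identity genes, and the PC3 interferon median was -0.338.

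Median centring without loess moved the median of all genes from 0.021 to 0.042 in LNCaP and from 0.006 to 0.104 in PC3. It gave 103 genes lower in LNCaP, 115 higher and 49 lower in PC3, 6 higher and 18 lower in both lines, and r = 0.437. Medians in LNCaP were 0.369 for NF-kB, -0.288 for stress response, -0.957 for ribosomal and -0.549 for LNCaP identity genes. In PC3 they were 0.531 for mitosis, 0.323 for DNA replication, -0.086 for interferon and -0.044 for histone genes. The NF-kB median there turned from -0.105 to 0.021, still below the 0.104 of all PC3 genes.

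In the authors' deposited log2 values, 4 genes were 2-fold higher in both lines, r was 0.314, and LNCaP medians were 0.059 for epithelial, -0.108 for ribosomal and -0.544 for LNCaP identity genes. Averaging all probes of a gene gave 31 genes lower in LNCaP, 17 lower in PC3 and 1 lower in both lines, r = 0.310, STMN1 at -1.84 in LNCaP and -1.69 in PC3, and 0 genes past limma's adjusted threshold, where 2033 had an unadjusted p under 0.05. Its medians were 0.386 for NF-kB and -0.096 for LNCaP identity genes in LNCaP, and -0.142 for interferon and 0.355 for hypoxia genes in PC3.

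Without a filter on dim probes r was 0.307, and LNCaP medians were 0.067 for interferon, 0.164 for NF-kB, 0.207 for TGF-beta and BMP, 0.057 for invasion, 0.017 for neuroendocrine and 0.161 for PC3 identity genes. With both channels above background 1 gene was higher in both lines, and LNCaP medians were 0.373 for TGF-beta and BMP and 0.084 for neuroendocrine genes. At 3-fold there were 46 genes higher and 7 lower in LNCaP, 1 and 3 in PC3, and 0 higher and 1 lower in both lines, as a stricter rule gives. Over other probes the mitosis median was -0.456 in LNCaP and 0.136 in PC3, against -0.312 and 0.36 for the probes used of the same 7 genes. The counts without background correction, with the scanner p-value as a filter and with an intensity trend in limma stayed within 1.5 times.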

Other observations

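The list of other heat shock genes was drawn up only after HSPA6 and CRYAB were seen, and the dye test of the changes common to both lines was chosen after its result was seen. The test of PC3 cells in the LNCaP culture and that of the covariance across probes were also added later. Both were set down before their own results.

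Genes of the heat shock response were higher in LNCaP well beyond HSPA6 and CRYAB. Of 22 other measured members, 21 lay above 0, and 6 were at least 2-fold higher: the co-chaperone DNAJB1 at 2.05, HSPB8 at 1.73, HSPA1A (near-identical to HSPA1B) at 1.67, HSPH1 at 1.47, HSP90AA1 at 1.29 and HSPB1 at 1.15. BAG3 stood at 0.95 and DNAJB4 at 0.98. In PC3 the same list had a median of 0.12 (percentile 96.7 of random lists, 14 of 23 above 0), with none at 2-fold, HSPH1 at -0.46 and HSPB1 at 0.62.

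A candidate explanation for HSPA6 and CRYAB is a heat shock response of the LNCaP knockdown culture. The other heat shock genes had a median of 0.61 in LNCaP, above all 10000 random lists, in a test that could have come out the other way. Whether such a response follows from lower STMN1 or from the handling of that culture stays open with 1 array. Without heat shock genes, 155 genes were at least 2-fold higher in LNCaP, against 163 with them.

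Genes typical of PC3 were higher in LNCaP, which raised the question of PC3 cells mixed into the LNCaP knockdown culture. The VIM value would need 1.09% PC3 cells. At that share, 40 genes abundant in PC3 and at background in the LNCaP control would have log2 ratios of at least 0.75 (median 1.19). Their median was 0.037, with 0 of 40 at the predicted value, which argues against such a mixture.

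Changes common to both lines were smaller when read across different probes of a gene. Over 4993 genes with at least 2 probes, 27.8% of the covariance between lines was kept across probes (95% bootstrap range 22.4 to 32.7), against 61.1% of the variance within LNCaP (58.4 to 63.8) and 29.5% within PC3 (26.6 to 32.5). The share kept between lines lay below that of LNCaP, and its range overlapped that of PC3. The shares are unlike, because noise of a single array lowers the share within a line and not that between lines. Such noise does not account for the low share kept between lines. Most of the covariance between lines for the same probe (0.0353) was thus tied to the probe. The comparison cannot tell dye bias from other differences between probes of a gene, so the part of dye bias stays open. Between lines, r was 0.386 for the same probe and 0.108 across different probes. The covariance between lines across probes was 0.00982 (0.00753 to 0.0121), above 0, which a change of the transcripts in both lines would give. With the same dye orientation on both arrays, a dye effect common to all probes of a gene would give it too. A value above 0 therefore does not separate the 2. No array with swapped dyes was made, which keeps the question open for each gene.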
